A study of Mus musculus with 4 samples.

How the data were processed

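The 4 libraries of CD45-enriched mouse kidney cells were 3′ droplet libraries, 1 for each genotype and day. The deposited files hold raw UMI counts per gene and barcode, unfiltered, with no normalization. Per the submitters' processing notes, reads were processed with Cell Ranger 7.0.1 on mm10, while the header of each matrix names Cell Ranger 4. Whether intronic reads were counted, and the pooling and sequencing batches, are not given in the sources used here. Both KO library titles share a number prefix that the WT titles lack, and whether it marks a batch is not given either. Gene coordinates, intron lengths and overlaps were taken from GENCODE M21 on mm10, with intron length as the part of the gene not covered by any exon.

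Barcodes with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs were kept. The mitochondrial limit removed 12.6% of such barcodes in WT day 1, 23.0% in KO day 1, 13.7% in WT day 3 and 16.4% in KO day 3. Doublets were called per library with Scrublet in scanpy 1.11.5, and where the automatic threshold marked under 0.5% of a library the top scores at 0.8% per 1000 cells were removed, which was the case in both WT libraries. This marked 5.06% of cells in WT day 1, 8.91% in KO day 1, 7.66% in WT day 3 and 13.5% in KO day 3. All 36144 remaining cells were clustered together without integration, on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), giving 44 clusters. Clusters were named from marker lists of 19 classes, 12 of them immune, fixed before the data were examined, and a name ending in -like says no more than that. A class needed at least 3 raised markers, and 6 clusters kept no name. The rule was extended after the data were seen, so that a cluster whose cells scored nearly alike for 2 immune classes stays unnamed (cluster 34, with 105 cells of KO day 1 and 79 of KO day 3). Macrophage-like, neutrophil-like, monocyte-like, conventional dendritic, T, B and natural killer cells fell largely into separate clusters by genotype, while the other named classes largely shared clusters.

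UMI counts were summed over the cells of a class in each library. The sums were scaled over the 4 libraries with TMM (edgeR 4.0.16, R 4.3.3), and ratios are log2 of CPM (counts scaled to a common library total) plus 5, which pulls the ratios of scarce genes toward 0. Macrophage-like, neutrophil-like and monocyte-like cells were compared gene by gene, KO against WT at each day and day 3 against day 1 in each genotype. Shares of cells have exact Clopper-Pearson intervals, and differences of shares combine the 2 exact intervals. CPM values have exact Poisson intervals, and log2 ratios have intervals from the exact binomial share of the UMIs. All are 95% intervals for counting error only, and a count of 0 allows up to 3 counts. No p-value was computed, since cells of 1 library are not replicates.

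Gene lists were fixed before the data were examined, as were the filters, the comparisons, the cell markers, the rule for named genes and most alternative settings. The 26 lists cover efferocytosis receptors and bridging molecules, lysosome and phagosome, cholesterol efflux and lipid handling, apoptosis promoting, apoptosis opposing, pro-inflammatory macrophage genes, alternative macrophage genes, EGF family ligands and receptors, ERK feedback targets, cytokines and NF-kB targets, chemokines, interferon response, MHC class II presentation, complement, matrix and profibrotic, glycolysis and hypoxia, oxidative phosphorylation, proliferation, immediate early and dissociation response, heat shock, neutrophil granule proteins, mature and tissue neutrophil genes, extracellular trap and oxidative burst, and proximal tubule, red cell and platelet, and lymphocyte transcripts as signs of RNA from other cells. A member was measured at 20 CPM or more in 1 of the compared libraries. Each list is given as its median, the members above and below 0, an interval from 1000 Poisson redraws, and its percentile among 10000 random lists of the same size matched on mean expression.

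Genes are named by a fixed rule. In each comparison these are the 5 highest and 5 lowest ratios in macrophage-like and in neutrophil-like cells and the 4 highest and 4 lowest in monocyte-like cells. Candidates had at least 50 CPM and 100 UMIs in the higher library and at least 0.2 of the CPM of that library's empty droplets, and were not mitochondrial, ribosomal, haemoglobin, antigen receptor, unnamed model or sex-linked genes. The rule adds the 5 up and 5 down that kept their direction at both days, the 2 to 4 largest members of each described list, and 17 genes chosen beforehand (Egfr, its ligands, and efferocytosis and apoptosis genes), not all of which are reported here. Of the single genes it names, the text gives those with the largest ratios in each class.

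Ribosomal RNA-like genes are Gm42418, AY036118, Lars2 and Cmss1, whose spans hold such repeats in mm10. Free RNA was profiled from barcodes around the most common low UMI total of each library, and contamination was estimated as a median over proximal tubule transcripts. Both definitions were chosen after the data were seen. The estimates for macrophage-like cells were 2.82% in WT day 1, 3.97% in KO day 1, 4.39% in WT day 3 and 2.42% in KO day 3. The steps were tested on simulated data, where 50 of 50 genes planted at each fold size had the right direction in macrophage-like and in neutrophil-like cells. The simulated libraries were Poisson draws from a shared profile, with changes planted in genes at 50 CPM or more. They held no difference in introns, ribosomal RNA-like reads or cluster mix, so this checks the computation only. A list with no planted change reached percentile 98.0 with a median of 0.04, so an extreme percentile can come with a tiny shift.

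Alternatives for shares were UMI minimums of 300 and 1000, a mitochondrial maximum of 10%, doublets kept or removed at the expected rate, a Monte Carlo test against empty droplets at a false discovery rate of 1%, thinning to the shallowest library, resolution 2, clustering of each library on its own or without long-intron genes, mixed clusters named, and all kept cells as denominator. For ratios they were total CPM, median-of-ratios size factors (DESeq2 1.42.0), a prior of 1 CPM, no low filter, background subtraction, cells thinned to 500 UMIs, genes with under 10 kb of intron, and removal of the intron-length trend. The expected doublet rate, the clustering without long-intron genes, the naming of mixed clusters and both intron settings were chosen after seeing the data. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, numba 0.67.0 and matplotlib 3.10.9. Reads, RNA velocity, trajectories and cell-cell communication were not analysed here.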

Results

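Kidney leukocytes were profiled by droplet single-cell RNA sequencing after ischemic acute kidney injury in mice, with cells carrying the pan-leukocyte protein CD45 enriched on magnetic beads. EGFRf/f mice, whose epidermal growth factor receptor gene is flanked by loxP sites and intact, are called WT. CD11b-Cre:EGFRf/f mice, in which Cre recombinase acts in myeloid cells, are called KO. Each genotype gave 1 library at day 1 and 1 library at day 3, 4 libraries in all. Total depth was 61187415 unique molecular identifiers (UMIs, counted transcripts) in the WT day 1 library, 224083497 in KO day 1, 117076877 in WT day 3 and 80577576 in KO day 3. After filtering, 6004, 16490, 8837 and 4813 cells remained in the same order, with median UMIs per cell of 4116, 6475, 6044 and 4903. With 1 library per group, no difference could be set against the spread between animals, so no test was run and every 95% interval covers counting error only.

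The libraries differed in quality signs that do not follow the study's groups alone. Transcripts from ribosomal RNA-like genes made up a median of 15.2% of a cell's UMIs in WT day 1, against 1.57% in KO day 1, 2.96% in WT day 3 and 2.36% in KO day 3. Barcodes taken as empty droplets held 13.2% of the UMIs of the WT day 1 library, 3.85% in KO day 1, 3.98% in WT day 3 and 5.51% in KO day 3. Genes with over 50 kb of intron had higher KO to WT ratios than genes with under 2 kb of intron in macrophage-like cells, by 1.52 on the log2 scale at day 1 and 1.69 at day 3. The same gap was 1.66 and 2.64 in T cell-like cells and 1.99 and 2.37 in B cell-like cells, and between the days of a genotype it was -0.17 in WT and 0.01 in KO macrophage-like cells. Other classes had wider gaps between days, with -0.41 in WT and 0.54 in KO T cell-like cells. In WT neutrophil-like cells it was -0.69, against a KO to WT gap of 0.89 at day 1. In macrophage-like, T cell-like and B cell-like cells both KO libraries differ from both WT libraries in this relation to intron length, so it is confounded with genotype, and no reads were examined.

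**Figure D1:**
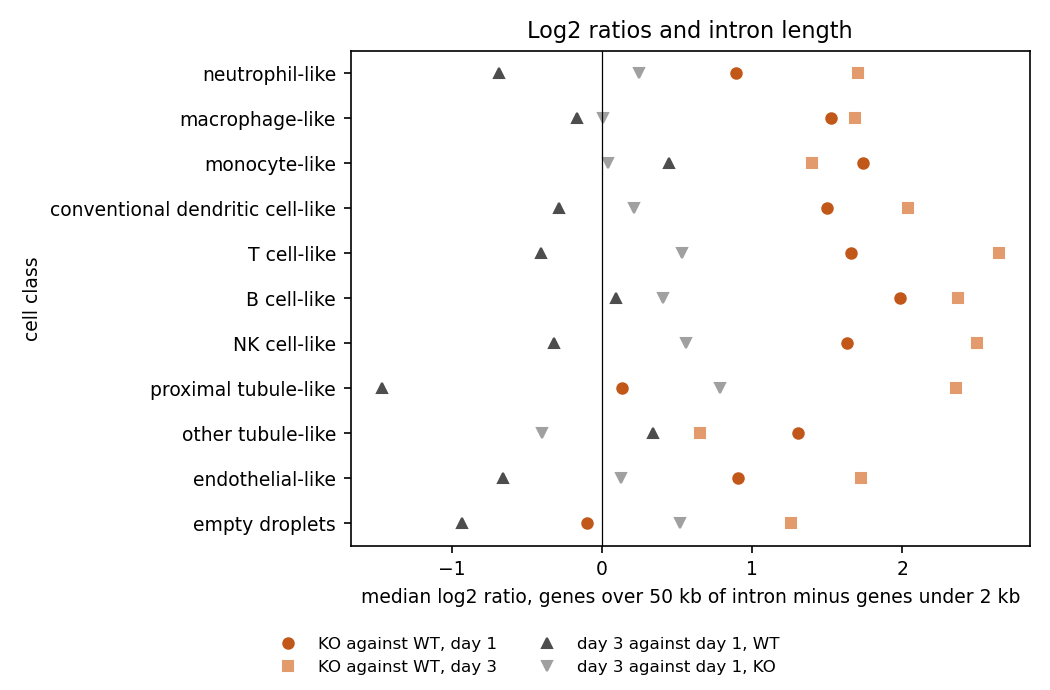
Gap between the median log2 KO to WT ratio of genes with over 50 kb of intron and that of genes with under 2 kb, by cell class and in empty droplets, for KO against WT at each day, with the same measure for day 3 against day 1 in each genotype. The KO to WT gap in T cell-like cells, 1.66 and 2.64, is at least as wide as in macrophage-like cells, 1.52 and 1.69.

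Egfr (chromosome 11, 16752203 to 16918158, mm10) was scarce in leukocytes of every library. Macrophage-like cells held 6 Egfr UMIs in WT day 1, 61 in KO day 1, 11 in WT day 3 and 6 in KO day 3, which is 1.05, 0.599, 0.222 and 0.572 CPM (counts scaled to a common library total). Neutrophil-like cells held 9, 1, 0 and 4 UMIs in that order, and the 0 in WT day 3 allows up to 0.676 CPM. Monocyte-like cells held 0, 0, 2 and 1. Empty droplets carried more in each library, at 11.7, 2.78, 1.29 and 7.44 CPM, and proximal tubule cells stood at 117, 186, 14.6 (1 UMI) and 276 CPM. The empty-droplet level times the estimated contamination lies below the lower interval end of the macrophage-like value in each library. The margin is narrow in WT day 1. The estimate has no interval, the macrophage-like values were TMM-scaled and the empty-droplet values were not, and doublets with tubule cells were not tested. The source of the macrophage-like counts therefore stays open. The product of empty-droplet level and contamination lies above the lower interval end in neutrophil-like cells and above the value in KO day 3 monocyte-like cells, so free RNA can account for those. The deleted exons are not given in the sources used here, and 3′ tags of a recombined transcript may lie outside the deleted part, so these counts check no label.

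Of the EGFR ligands, only Areg and Hbegf were seen beyond a few UMIs and beyond tubule background in myeloid classes. Areg (amphiregulin) stood at 28.8 CPM in KO day 3 macrophage-like cells, against 4.37 in WT day 3, 7.24 in KO day 1 and 6.81 in WT day 1, with 17.4 CPM in the empty droplets of KO day 3. In monocyte-like cells of KO day 3 it stood at 44.0 CPM. Hbegf was between 2.10 and 3.73 CPM in macrophage-like cells of all 4 libraries and at 13.5 CPM in WT day 3 neutrophil-like cells. Ereg, Tgfa and Btc had at most 15 UMIs in any of the 3 myeloid classes of any library. Egf itself, a product of distal tubules, reached 558 CPM in the empty droplets of KO day 1, and its KO to WT ratio of 1.38 in day 1 macrophage-like cells became -0.33 when background was subtracted.

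The comparison of KO with WT at day 1 asks whether leukocyte composition and the genes of dead-cell uptake (efferocytosis) and of neutrophil apoptosis differ early after injury when EGFR is targeted in myeloid cells. Neutrophil-like cells, the first phagocytes to enter injured tissue, were 5.52% of immune cells in KO (650 of 11767, 95% Clopper-Pearson interval 5.12 to 5.95) and 49.6% in WT (2504 of 5046, 48.2 to 51.0), a difference of -44.1 percentage points (-45.5 to -42.6). Macrophage-like cells went the other way, 61.9% in KO and 15.1% in WT, a difference of 46.8 points. Monocyte-like cells, their blood precursors, were 6.83% in KO and 17.2% in WT, a difference of -10.4 points. T cell-like cells were 9.57% and 8.68%, B cell-like cells 5.51% and 4.28%, natural killer cells 3.95% and 1.80%, conventional dendritic cells 4.78% and 2.91%, type 2 innate lymphoid cells 1.504% and 0.198%, and plasmacytoid dendritic cells 0.425% and 0.178%. No cluster was named as eosinophils, mast cells or basophils, or plasma cells in any library. Cells in clusters without a name were 22.9% of KO and 8.46% of WT cells, with 2893 and 395 of them in cluster 0, whose marker candidate was macrophage but which had low UMIs and scored highest for another class.

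**Figure D2:**
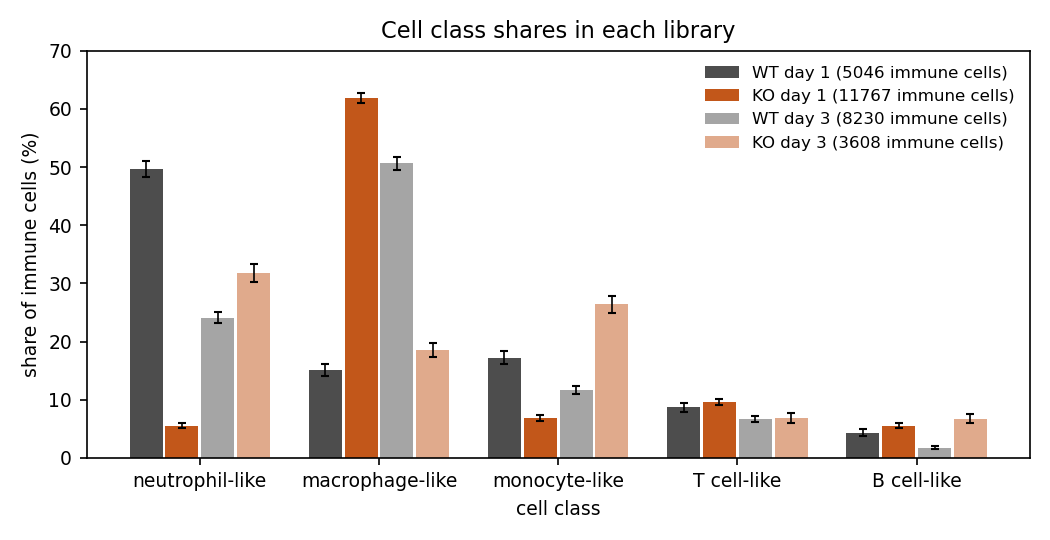
Share of immune cells, in percent, of neutrophil-like, macrophage-like, monocyte-like, T cell-like and B cell-like cells in each of the 4 libraries, with 95% Clopper-Pearson intervals for counting error. Neutrophil-like cells stand at 49.6% in WT day 1 and 5.52% in KO day 1, against 24.1% in WT day 3 and 31.7% in KO day 3.

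In macrophage-like cells at day 1, the KO library had more cell cycle transcripts and fewer transcripts of chemokines, matrix, stress and glycolysis than WT. The proliferation list had a median log2 ratio of 1.16 (1.05 to 1.28), with 19 genes above 0 and 3 below, above every random list matched on expression, led by the mitotic genes Ube2c at 2.87, Cenpf at 2.77 and Top2a at 2.33. The chemokine list, signals that draw leukocytes, had a median of -2.05 with 2 above and 15 below at percentile 0.0, including the neutrophil attractants Cxcl3 at -4.69 and Cxcl2 at -3.22. Immediate early genes, which tissue dissociation also induces, had a median of -1.36 with 0 above and 21 below, among them Fos at -2.28 and Dusp1 at -2.83. Matrix and profibrotic genes had a median of -1.04 (3 above, 17 below), with the matrix protein fibronectin, Fn1, at -2.37 and the protease inhibitor Timp1 at -3.04. Glycolysis and hypoxia genes stood at -1.04 (4 above, 20 below) with the lipid droplet gene Hilpda at -2.54, heat shock genes at -1.04 (2 above, 13 below), and oxidative phosphorylation genes at -0.73 (3 above, 38 below). With the intron-length trend removed, the glycolysis median shrank to -0.76 and that of heat shock to -0.48. The oxidative phosphorylation median lies near the -0.61 of all genes with under 2 kb of intron. Complement genes had a median of -0.94 (3 above, 9 below) at percentile 0.7, with the C5a receptor C5ar1 at -1.69. Interferon-response genes stood at 0.37 (22 above, 15 below), but over the members with under 10 kb of intron their median was -0.08.

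The efferocytosis list in day 1 macrophage-like cells had a median of 0.24 (0.17 to 0.29), with 15 genes above 0 and 12 below at percentile 99.2, but the median over its members with under 10 kb of intron was -0.99. Mertk and Axl, receptors that bind dying cells through bridging proteins, were at 1.45 (1.28 to 1.63) and 0.63 (0.52 to 0.74), their bridging ligands Gas6 at 0.43 and Mfge8 at 0.63, and the scavenger receptor Cd36 at 0.90. Mfge8 turned below 0 in thinned cells and Cd36 with the intron-length trend removed. The largest members by size were the bridging protein Thbs1 at -3.82, the engulfment adaptor Elmo1 at 2.80 and its partner Dock1 at 2.32. Lysosome genes had a median of -0.20 (10 above, 20 below), which turned to 0.18 under total CPM, and cholesterol and lipid genes -0.07 (7 above, 9 below). Pro-inflammatory genes had a median of -0.51 (5 above, 11 below) with the interleukin Il1b at -2.18, and alternative-activation genes -0.45 (5 above, 10 below; above 0 with each library clustered alone) with arginase, Arg1, at -2.97. MHC class II genes stood at 0.31 (6 above, 4 below) but turned below 0 under 3 of 14 settings, as low as -0.24. ERK feedback targets stood at -0.51 (3 above, 7 below) and cytokines and NF-kB targets at -0.34 (6 above, 12 below), which shrank to -0.0197 under 1 setting. EGF family genes had only 4 measured members, with a median of 0.09. Lists for RNA from other cells gave -1.36 for proximal tubule transcripts (0 above, 3 below), -0.06 for red cell and platelet transcripts (2 above, 2 below) and -1.76 for lymphocyte transcripts (1 above, 3 below).

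Among single genes, the lowest in KO against WT macrophage-like cells at day 1 were the acute phase protein Saa3 (chromosome 7, 46711998 to 46715700) at -5.96 (-6.04 to -5.89), the metal-binding Mt2 at -5.05, Cxcl3 at -4.69, Lhfpl4, a synaptic membrane protein, at -4.62 and the platelet chemokine Ppbp at -3.98. The highest were Lrmda, linked to pigment cell differentiation, at 5.40, the scaffold gene Gphn (chromosome 12, 78226379 to 78684772) at 4.99, the Notch coactivator Maml2 at 4.68, the histone deacetylase Hdac9 at 4.44 and the endosomal exchanger Slc9a9 at 4.35. Each of these 5 genes has over 50 kb of intron, and their ratios in T cell-like cells were 3.22, 5.82, 4.79, 2.74 and 4.57. The same gap in introns limits any reading of the genes that were higher in KO, and of short-intron genes that were lower. Genes with under 2 kb of intron had median KO to WT ratios below 0 at day 1 and day 3. These were -0.61 and -0.93 in macrophage-like, -0.59 and -0.54 in neutrophil-like and -0.72 and -0.48 in monocyte-like cells.

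Neutrophil-like cells at day 1 carried lower immediate early, cytokine and maturation transcripts in KO than in WT. Immediate early genes had a median of -1.23 with 0 above and 22 below, mature and tissue neutrophil genes -1.13 (1 above, 26 below) with the chemokine receptor Cxcr2 at -2.18, and granule proteins, made early in neutrophil development, -1.26 (5 above, 14 below) with the collagenase Mmp8 at -2.70. Cytokines and NF-kB targets had a median of -1.25 (5 above, 15 below), with the feedback inhibitor Tnfaip3 at -2.15. Apoptosis-promoting genes had a median of -0.34 (-0.51 to -0.17; 5 above, 10 below; percentile 44.3) and apoptosis-opposing genes -0.37 (-0.56 to -0.25; 5 above, 12 below; percentile 54.2), and under total CPM they turned to 0.39 and 0.36. The short-lived survival factor Mcl1 stood at -1.02, the pore-forming Bax at 0.31 and the death receptor Fas at -0.36. Bax turned below 0 in thinned cells, and Fas above 0 under total CPM. Extracellular trap and oxidative burst genes had a median of -0.73 (3 above, 10 below) and glycolysis genes -0.76 (4 above, 22 below), both above 0 under total CPM. MHC class II genes, which neutrophils hardly express, had a median of 2.49 with 9 above and 0 below, and the macrophage complement genes C1qa, C1qb and C1qc were at 2.71, 2.71 and 2.74. Such transcripts of other cells limit the reading of the lower neutrophil lists in KO, and their share in those medians was not tested. The doublet step marked 8.91% of KO day 1 cells, against 14.5% expected.

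For single genes in day 1 neutrophil-like cells, the lowest in KO were the MHC class I gene H2-Q10 at -5.64, the chitinase-like Chil3 at -4.93, Lars2, a mitochondrial enzyme gene in which ribosomal RNA-like reads collect, at -4.83 and the lipase Lipg at -3.83. Lhfpl4 had 0 UMIs in KO and 469 in WT, which is 61.9 CPM. It was present in WT day 1 alone in 4 classes, with 2.03 CPM in WT day 3 macrophage-like cells. Its day 1 ratios therefore do not separate KO from WT. H2-Q10 was likewise much lower in WT day 3 than in WT day 1 neutrophil-like cells, so neither does its ratio. The highest were Cmss1, whose span holds ribosomal RNA-like repeats, at 7.66, Gphn at 6.57, Lrmda at 4.87, the kinase gene Camk1d at 4.76 and the myosin Myo1d at 4.13. An estimated 9.08% of the UMIs of KO neutrophil-like cells came from free RNA, against 5.06% in WT. This estimate rests on proximal tubule transcripts and does not count doublets.

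Monocyte-like cells of WT day 1 lay in clusters 15 (443 of 870) and 9 (423) and those of KO day 1 mostly in cluster 5 (745 of 804), so the mix of monocyte types differed. Interferon-response transcripts were higher in KO, with a median of 0.79 (0.66 to 0.88), 25 above and 3 below at percentile 99.9, and the antiviral Rsad2 at 1.63. Oxidative phosphorylation genes had a median of -1.19 with 0 above and 41 below, matrix genes -0.98 (2 above, 13 below), glycolysis genes -0.75 (8 above, 16 below) and neutrophil granule proteins -1.12 (3 above, 9 below). The lowest genes were Saa3 at -6.31, the iron-carrier binder Lcn2 at -5.00 and Wfdc21, a small secreted inhibitor, at -4.86, with 0 UMIs of Lhfpl4 in KO against 1371 in WT. The highest were Gphn at 5.95, Lrmda at 5.43, the phosphodiesterase Pde7b at 4.90 and the receptor adaptor Gab2 at 4.74. Scaling by total CPM shifted the median of all genes relative to TMM by 0.36 in macrophage-like, 0.74 in neutrophil-like and 0.45 in monocyte-like cells at day 1, so list medians near those sizes depend on the scaling.

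At day 3 the comparison of KO with WT asks the same question later in recovery. Macrophage-like cells were 18.5% of immune cells in KO (668 of 3608) and 50.6% in WT (4168 of 8230), a difference of -32.1 percentage points that shrank to -11.4 with each library clustered alone and to -11.5 at a UMI minimum of 300. Neutrophil-like cells were 31.7% in KO and 24.1% in WT, a difference of 7.62 points (5.84 to 9.42) that turned negative under 3 of 12 other settings. Monocyte-like cells were 26.4% and 11.7%, a difference of 14.7 points that shrank to 6.72 at a UMI minimum of 300. B cell-like cells were 6.74% in KO and 1.75% in WT, T cell-like cells 6.87% and 6.66%, natural killer cells 3.96% and 2.67%, conventional dendritic cells 4.13% and 2.13%, type 2 innate lymphoid cells 1.497% and 0.122%, and plasmacytoid dendritic cells 0.194% and 0.231%. Unnamed clusters held 21.1% of KO and 5.62% of WT cells, most of them in cluster 0 (910 of 1017 and 393 of 497), so KO had more cells in this macrophage-candidate cluster than the 668 named macrophage-like.

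Macrophage-like cells at day 3 differed between the genotypes in the cell cycle and in several immune lists. Proliferation genes had a median of -2.35 (-2.46 to -2.27) with 0 above and 30 below at percentile 0.0, including Mki67, a marker of dividing cells, at -3.37 and Birc5 at -3.57. Interferon-response genes had a median of -1.23 (3 above, 30 below) with Irf7 at -2.61 and Isg15 at -2.18, oxidative phosphorylation genes -1.09 (0 above, 41 below) and glycolysis genes -1.23 (3 above, 22 below). The oxidative phosphorylation median lies near the -0.93 of all genes with under 2 kb of intron. Alternative-activation genes stood at -1.46 (4 above, 12 below) with the lectin Clec10a at -3.41 and the folate receptor Folr2 at -3.11. This median ranged from -2.35 to -0.13 over 14 settings. Cytokines and NF-kB targets had a median of 1.00 (13 above, 5 below) with Tnf at 2.69 and Nfkbiz at 2.26, and pro-inflammatory genes 0.83 (10 above, 7 below) with the costimulator Cd86 at 2.03 (as low as 0.0125 under 1 setting). ERK feedback targets stood at 0.65 (8 above, 2 below) with Spred2 at 2.21. The EGF family list had 5 members above 0 and 0 below at a median of 0.79, which shrank to 0.0424 under 1 setting, with the EGFR ligand Areg (chromosome 5, 91139599 to 91148432) at 1.85 (1.69 to 2.01) and the feedback inhibitor Errfi1 at 2.13. Immediate early genes had a median of 0.34 (12 above, 8 below) and granule proteins -2.08 (0 above, 10 below), which shrank to -0.28 under 1 setting.

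The efferocytosis list at day 3 had a median of -0.06 (-0.12 to -0.03; 12 above, 16 below; percentile 99.04) in macrophage-like cells and was above 0 under total CPM, under size factors and after thinning. The percentile was not matched on intron length, and the median over members with under 10 kb of intron was -0.38. Mertk was at 0.99, Axl at 0.66 and Cd36 at 1.77, while Gas6 was at -1.34 and Mfge8 at -1.26. Lysosome genes had a median of -0.67 (2 above, 28 below), cholesterol and lipid genes -0.24 (7 above, 11 below), chemokines -0.12 (7 above, 11 below), complement genes -0.15 (6 above, 7 below) and matrix genes -0.65 (9 above, 12 below), all turning above 0 under total CPM. Apoptosis-promoting genes were at -0.65 (3 above, 16 below) and apoptosis-opposing genes at 0.43 (14 above, 6 below), with the survival gene Bcl2 at 2.51 and Bcl2l1 at 2.07. Genes of the extracellular trap and oxidative burst list had a median of -1.14 (0 above, 13 below), heat shock genes 0.10 (8 above, 7 below; below 0 over members with under 10 kb of intron), MHC class II genes -0.02 (5 above, 5 below) and mature neutrophil genes 0.09 (12 above, 9 below). The lowest single genes were the lipid carrier Fabp5 at -4.91, the secreted Wfdc17 at -4.62, the histone Hist1h2ap at -4.55, the lysophospholipase Gdpd3 at -4.35 and Ifi202b, an interferon-induced gene with 1 UMI in KO and 12133 in WT, at -5.61 (-5.64 to -5.49). The highest were Gphn at 5.41, Tex14 at 4.99, the microRNA host gene Mir142hg at 4.604, the class II gene H2-Eb1 at 4.55 and the actin regulator Fmnl2 at 4.32. Gdpd3 was present and H2-Eb1 near absent in WT day 3 alone, in 6 and 5 of 7 classes, T cell-like cells included for Gdpd3. Ifi202b was unseen in WT day 1 macrophage-like cells too. The ratios of these genes therefore do not separate KO from WT, and the Gdpd3 ratios below share this limit.

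**Figure D3:**
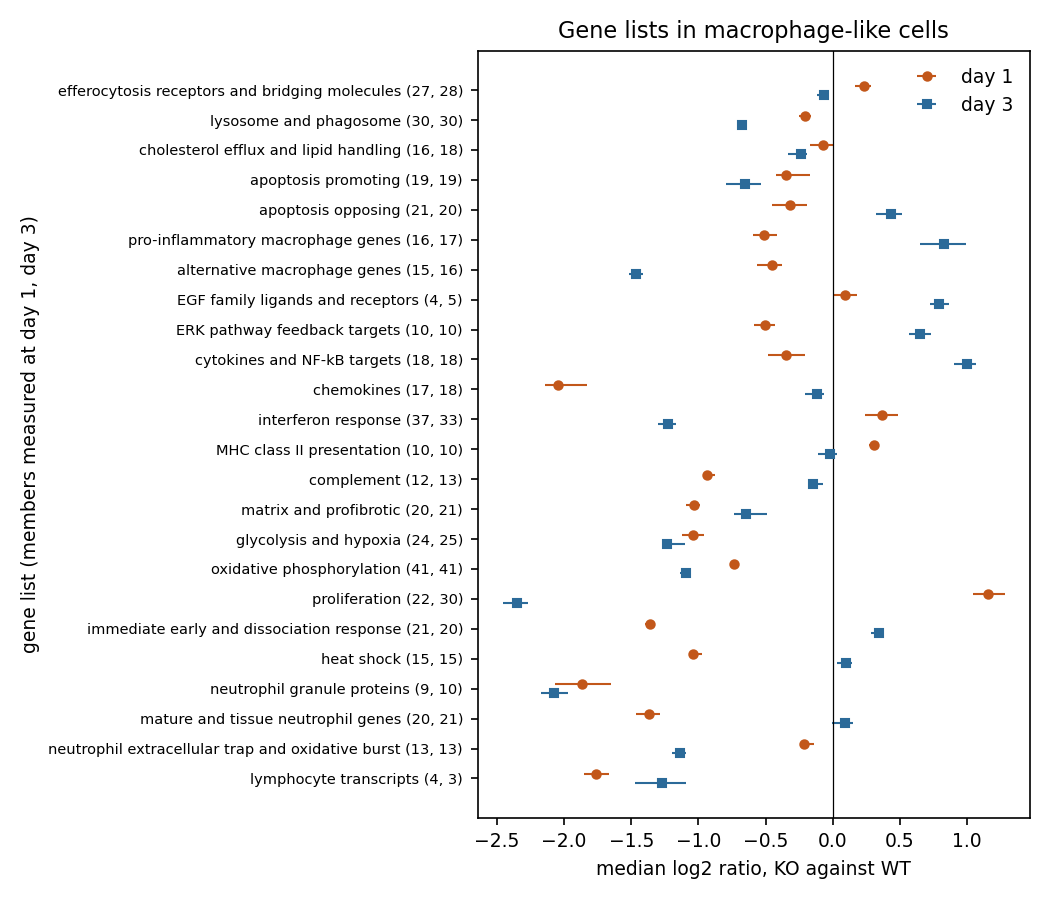
Median log2 KO to WT ratio of each gene list in macrophage-like cells at day 1 and day 3, with intervals from 1000 Poisson redraws. Proliferation stands at 1.16 at day 1 and -2.35 at day 3, and the medians of lysosome, apoptosis and extracellular trap genes at day 1 and of efferocytosis, lysosome, cholesterol, chemokine, complement and matrix genes at day 3 change sign under total CPM.

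Neutrophil-like cells at day 3 had lower energy transcripts and higher cytokine and pro-inflammatory transcripts in KO. The chemokine median ranged from -0.60 to 0.37 over the settings, so it had no firm direction. Glycolysis and hypoxia genes had a median of -1.54 (7 above, 20 below) with the hexokinase Hk2 at -3.26, and oxidative phosphorylation genes -0.81 (1 above, 39 below). All genes with under 2 kb of intron stood at -0.54 there, which limits the reading of the latter. Cytokines and NF-kB targets had a median of 0.95 (16 above, 4 below), and pro-inflammatory genes 0.87 (13 above, 5 below) with Acod1, which makes itaconate, at 4.58. Apoptosis-promoting genes had a median of -0.33 (-0.44 to -0.12; 6 above, 8 below; percentile 4.6; above 0 with the intron-length trend removed) with the mitophagy gene Bnip3 at -2.81 and the death activator Bcl2l11 at 2.58, and apoptosis-opposing genes 0.54 (0.29 to 0.59; 12 above, 5 below; percentile 74.3) with Bcl2l1 at 3.30. The latter median shrank to 0.0471 with each library clustered alone. Mcl1 was at 0.03, Bax at -1.26 and Fas at 0.52. Granule proteins had a median of 0.25 (12 above, 6 below; as low as 0.0174 under 1 setting) and mature neutrophil genes 0.54 (17 above, 11 below), the latter below 0 over members with under 10 kb of intron. The highest single genes were Cmss1 at 8.47, Aig1 at 8.42, Gphn at 7.90, Btbd9 at 5.90 and Thbs1 at 5.86. Aig1 was also far higher in KO day 3 than in KO day 1, so its ratio may mark that library rather than the genotype. The lowest were Gdpd3 at -5.93, the protease inhibitors Cstdc5 at -5.53 and Stfa2 at -4.56, the hypoxia-induced Fam162a at -4.16 and Echdc3 at -3.91.

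Monocyte-like cells at day 3 had higher activation and lower interferon transcripts in KO. However, WT cells lay mostly in cluster 9 (695 of 964) and KO cells in cluster 5 (914 of 952), so different monocyte types are set against each other. Immediate early genes had a median of 1.22 (21 above, 1 below) with the nuclear receptor Nr4a2 at 4.20, pro-inflammatory genes 1.22 (13 above, 4 below) with the prostaglandin enzyme Ptgs2 at 2.96, matrix genes 1.10 (14 above, 2 below) with Thbs1 at 3.42, and EGF family genes 1.42 (6 above, 0 below), which shrank to 0.16 under 1 setting. The pro-inflammatory median was as low as 0.33 and the matrix median as low as 0.23. Areg had 488 UMIs in KO, which is 44.0 CPM, and 0 in WT. Interferon-response genes had a median of -1.03 (1 above, 27 below) with Gbp2 at -2.06, and oxidative phosphorylation genes -0.61 (0 above, 41 below), the latter near the -0.48 of all genes with under 2 kb of intron. Single genes at the top were Cmss1 at 7.26, Gphn at 6.51, Lrmda at 5.55 and Mir142hg at 5.22, and at the bottom Ifi202b at -5.46, Gdpd3 at -3.30, the creatine enzyme Gatm at -3.18 and Chil1 at -3.06. Total CPM shifted the median of all genes by 0.62, -0.17 and 0.18 in macrophage-like, neutrophil-like and monocyte-like cells at day 3.

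Several genes differed in the same direction at both days. Lower in KO macrophage-like cells at day 1 and day 3 were the alternative-activation genes Chil3 (-3.87 and -3.22), the lectin Mgl2 (-2.59 and -3.69), Arg1 (-2.97 and -2.56), Wfdc17 (-2.46 and -4.62) and the coagulation factor F10 (-2.84 and -2.41). Higher at both days were Gphn, Maml2, Hdac9, Gab2 (4.05 and 4.07) and Lrmda, which are all long-intron genes. In neutrophil-like cells Hk2 (-1.98 and -3.26), the stress factor Xbp1 (-2.25 and -1.94), Oser1 (-1.60 and -2.27), the adaptor Myd88 (-1.85 and -1.59) and Ier3 (-1.96 and -1.57) were lower at both days, and Cmss1, Gphn, Lrmda, Camk1d and Myo1d were higher. Hk2 in T cell-like cells was at 0.27 and 0.40, so its lower level was not shared with that class.

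The comparison of day 3 with day 1 within WT asks how leukocytes change as kidneys of the control genotype recover. Macrophage-like cells went from 15.1% to 50.6% of immune cells, a difference of 35.6 percentage points, while neutrophil-like cells went from 49.6% to 24.1% (-25.5 points) and monocyte-like cells from 17.2% to 11.7% (-5.53 points). Over other settings these changes shrank to 27.8, -14.3 and -1.95 points at the least. In macrophage-like cells the proliferation list had a median of 2.06 (1.97 to 2.16) with 30 above and 0 below, and oxidative phosphorylation 0.56 with 41 above and 0 below. Alternative-activation genes had a median of 0.83 (12 above, 5 below) with Folr2 at 3.24 and the lysosomal Gpnmb at 3.04, and lysosome genes 0.49 (19 above, 10 below) with the protease Ctsd at 1.90. Pro-inflammatory genes had a median of -0.69 (5 above, 11 below) with Il1b at -2.06, cytokines and NF-kB targets -0.85 (5 above, 13 below), immediate early genes -0.90 (1 above, 20 below) and chemokines -0.44 (7 above, 11 below), which turned to 0.75 with each library clustered alone. Efferocytosis genes had a median of 0.20 (18 above, 10 below; below 0 over members with under 10 kb of intron) with the lipid receptor Trem2 at 1.70, and the bridging ligands Gas6 and Mfge8 were at 1.27 and 1.22. Red cell and platelet transcripts were at -3.02 (0 above, 4 below). The lowest single genes were H2-Eb1 at -6.37, AA467197 at -4.33 and Saa3 at -4.29. The highest was Syngr1 at 4.29, and Ifi202b had 0 UMIs at day 1 and 12133 at day 3. H2-Eb1 was near absent in WT day 3 alone, in 5 classes, and Ifi202b was hardly seen in KO day 3 either. The changes of H2-Eb1 and Ifi202b may therefore mark a library rather than recovery.

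In WT neutrophil-like cells, granule proteins were lower at day 3 than at day 1, with a median of -2.03 (1 above, 18 below), Ngp at -4.90 and the antimicrobial Camp at -3.66. Interferon-response genes had a median of -1.20 (4 above, 27 below) with Ifit1 at -2.84, and glycolysis and hypoxia genes 0.95 (21 above, 6 below) with the redox enzyme Ero1l at 2.72. Apoptosis-promoting genes had a median of 0.34 (9 above, 6 below) and apoptosis-opposing genes -0.18 (7 above, 10 below), the latter turning above 0 under total CPM, in thinned cells and over members with under 10 kb of intron, where it was 0.55. Gdpd3 was the highest single gene at 4.95, and Rdh12 at -5.84, Thbs1 at -5.35 and H2-Q10 at -5.07 the lowest. Trim12a had 0 UMIs at day 3 and 1027 at day 1. In WT monocyte-like cells, whose part in cluster 9 went from 423 of 870 at day 1 to 695 of 964 at day 3, interferon-response genes had a median of 0.92 (27 above, 1 below) with Oas1a at 1.71, and immediate early genes -0.96 (0 above, 22 below), while H2-Eb1 at -5.26, Lhfpl4 at -5.00, Lcn2 at -4.94 and the alarmin S100a8 at -4.46 were lowest. Across several classes, Lhfpl4 was present in WT day 1 alone, Gdpd3 was present in WT day 3 alone, and Trim12a and H2-Eb1 were near absent there. H2-Q10 was low in KO day 1 neutrophil-like cells too. The changes of these genes may therefore mark a library rather than recovery. Total CPM shifted the median of all genes by -0.15, 0.44 and 0.21 in macrophage-like, neutrophil-like and monocyte-like cells between the WT days.

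The comparison of day 3 with day 1 within KO asks how the same course runs when EGFR is targeted in myeloid cells. Macrophage-like cells went from 61.9% to 18.5% of immune cells, a difference of -43.4 percentage points, while neutrophil-like cells went from 5.52% to 31.7% (26.2 points) and monocyte-like cells from 6.83% to 26.4% (19.6 points). With each library clustered alone the changes shrank to -23.4 points in macrophage-like and 10.99 in neutrophil-like cells. In macrophage-like cells the proliferation list had a median of -2.05 (-2.13 to -1.92; 3 above, 19 below) with Mki67 at -3.32 and Cenpf at -3.09. Chemokines had a median of 1.67 (15 above, 3 below) with Cxcl3 at 3.68 and Cxcl2 at 2.87, matrix genes 1.11 (15 above, 3 below) with Thbs1 at 3.06, heat shock genes 0.82 (15 above, 0 below) and ERK feedback targets 0.91 (10 above, 0 below). Interferon-response genes had a median of -1.11 (1 above, 31 below) with the interferon-induced chemokine Cxcl9 at -3.55. MHC class II genes stood at -0.95 (1 above, 9 below) with their activator Ciita at -2.24. Efferocytosis genes had a median of 0.02 (15 above, 11 below), with Mertk at -0.45, Axl at 0.02 and Cd36 at 1.54. Immediate early genes were at 0.74 (19 above, 1 below) and red cell and platelet transcripts at -2.10 (1 above, 3 below).

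In KO neutrophil-like cells, cytokines and NF-kB targets had a median of 1.45 with 20 above and 0 below at day 3 against day 1, immediate early genes 1.30 (23 above, 0 below) and mature neutrophil genes 1.34 (27 above, 0 below). The chemokine genes Cxcl3 at 3.88 and Ccl4 at 2.99 were among the highest, with Aig1 at 7.72. MHC class II genes had a median of -2.03 (0 above, 9 below) with H2-Ab1 at -3.05 and Cd74 at -2.79, and the lipid carrier Apoe was at -2.65. These are hardly neutrophil transcripts, so the limit from transcripts of other cells at day 1 applies here too. Apoptosis-opposing genes had a median of 0.92 (12 above, 5 below), as low as 0.29 over the settings. Apoptosis-promoting genes stood at 0.22 (10 above, 4 below), but below 0 under total CPM and over members with under 10 kb of intron. In KO monocyte-like cells, matrix genes had a median of 1.29 (15 above, 1 below), glycolysis genes 0.37 (25 above, 0 below), interferon-response genes -0.77 (0 above, 27 below) and MHC class II genes -1.05 (1 above, 8 below). The highest genes there were Chil3 at 3.21, Lcn2 at 3.17 and Saa3 at 3.16, and the lowest Tmcc3 at -2.30, the tetraspanin Cd81 at -2.08, the mannose receptor Mrc1 at -1.95 and Hdac9 at -1.80. Total CPM shifted the median of all genes by 0.12, -0.47 and -0.06 between the KO days.

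**Figure D4:**
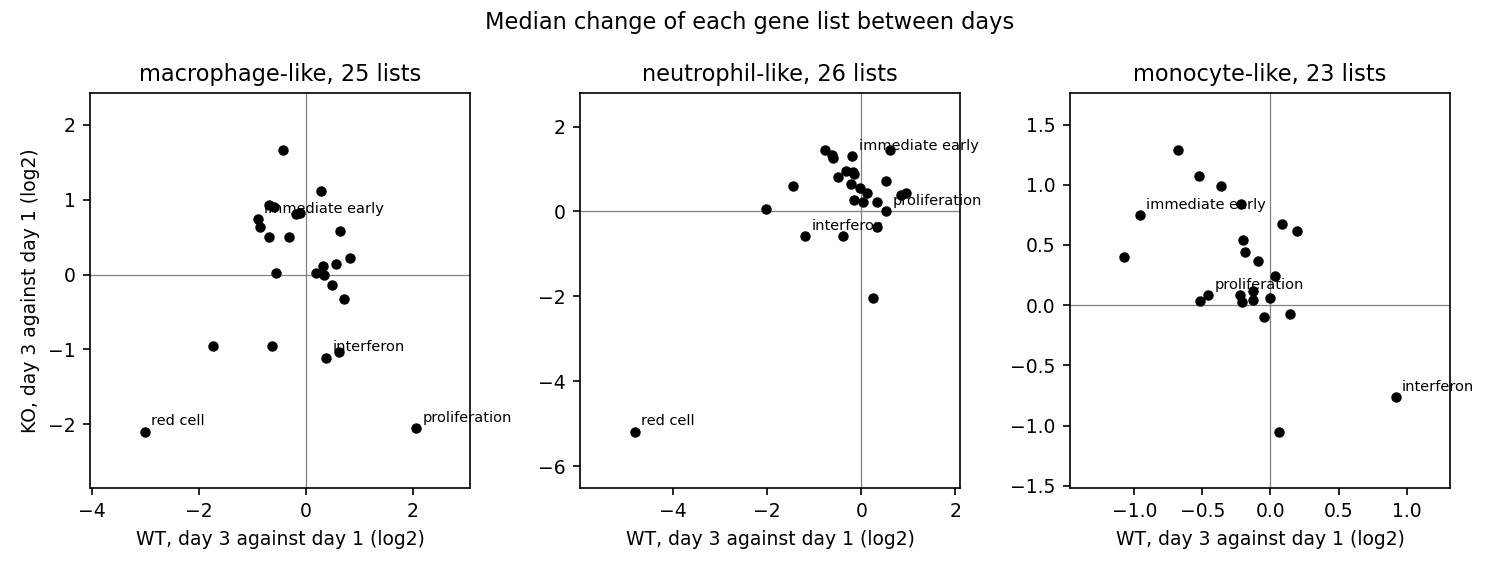
Median day 3 against day 1 log2 ratio of each gene list in WT (horizontal axis) and in KO (vertical axis), 1 panel per class and 1 point per list. Proliferation in macrophage-like cells is at 2.06 in WT and -2.05 in KO, and several lists near 0 change sign under total CPM.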

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

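The tests of the cell filter, doublets and unnamed clusters, and of a recovery running ahead in KO, were chosen only after the shares were seen. Each result here is set apart because KO and WT differed in opposite directions at day 1 and day 3, with 1 library behind each value, and the difference between the days was not tested. The KO minus WT difference in the share of neutrophil-like cells was -44.1 percentage points at day 1 and 7.62 at day 3, the latter turning negative under 3 of 12 other settings. In macrophage-like cells it was 46.8 and -32.1 points, and in monocyte-like cells -10.4 and 14.7. Efferocytosis genes in macrophage-like cells had a median log2 ratio of 0.24 at day 1 and -0.0616 at day 3, which turned above 0 under total CPM and size factors. The median of all genes was -0.03 and -0.26, so the list lay above it at both days. Over genes with under 10 kb of intron both list medians were below 0, at -0.99 and -0.38, so the opposition disappears. Apoptosis-opposing genes in neutrophil-like cells had a median of -0.37 at day 1, close to the -0.33 of all genes and above 0 under total CPM, and 0.54 at day 3, which shrank to 0.0471 with each library clustered alone.

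The shares went opposite ways between the days in the 2 genotypes, with neutrophil-like cells at -25.5 points in WT and 26.2 in KO. No setting raised the mitochondrial limit, which removed 23.0% of barcodes in KO day 1, so losses to that limit stay open. No setting gave every unnamed cluster a class, so losses to the unnamed clusters were covered only in part. Losses to the UMI minimum or the doublet step are argued against. The smallest of the changes in neutrophil-like and macrophage-like shares over 13 settings was 10.9854 points in its own direction. The same value, the smallest KO increase in neutrophil-like share, goes against a KO recovery that runs ahead of WT, though it is the change that prompted the test and rests on 1 library per day. An exchange of the day labels between the KO libraries stays open as a hypothesis, and so does the same exchange between the WT libraries, which would give the same value: across genes with little intron, day changes in WT and KO had a median Spearman correlation of -0.2997 over 7 classes (5 below -0.1, 0 above 0.1, genes not being independent replicates). Among such genes changed by over 1 on the log2 scale in both genotypes, 79 of 87 moved in opposite directions in macrophage-like cells and 6 of 17 in B cell-like cells. Red cell and platelet transcripts moved the same way in both genotypes in the leukocytes that carried the most of them. They were lower at day 3 in neutrophil-like (-4.82 in WT and -5.18 in KO) and macrophage-like cells (-3.02 and -2.10). In empty droplets they were higher (haemoglobin from 0.005% to 0.0263% in WT and from 0.0185% to 0.0726% in KO). In T cell-like cells, where haemoglobin was scarce, it went from 0.0006% to 0.0007% in WT and from 0.0031% to 0.0013% in KO. This list alone therefore speaks only weakly against an exchange. Free RNA shared by all classes may add to the correlation, which was -0.629 in empty droplets. A different course in KO kidneys, such as a delayed one, stays open and untested, and the labels were used as given.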

How the results depend on the processing

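The settings with doublets removed at the expected rate, clustering without long-intron genes, mixed clusters named and both intron settings were chosen after the results were seen, as were all alternatives of the day 3 minus day 1 shares. Shares were rerun under 12 settings, lists under up to 14 and single genes under 7, and the cause of each shift was not tested unless stated. In brackets, day 1 and day 3 stand for KO minus WT or KO against WT at that day, and WT and KO for day 3 against day 1 within that genotype. Direction of the share differences held in all settings except 3 for neutrophil-like cells at day 3, and naming of mixed clusters left all 12 share results close to their values.

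Share differences that moved or turned, in percentage points, were as follows. With a UMI minimum of 300, the values were neutrophil-like -40.9 (day 1), -0.272 (reversed, day 3), -22.5 (WT), 18.2 (KO), macrophage-like 45.3 (day 1), -11.5 (day 3), 27.8 (WT), -29.1 (KO) and monocyte-like -8.38 (day 1), 6.72 (day 3), -1.95 (WT), 13.2 (KO). Under a UMI minimum of 1000, the values were neutrophil-like -36.7 (day 1), -20.9 (WT), 22.1 (KO) and macrophage-like 36.8 (day 1), -26.98 (day 3), 32.3 (WT), -31.5 (KO). Given a mitochondrial maximum of 10%, the values were neutrophil-like -46.3 (day 1), 3.84 (day 3), macrophage-like 37.3 (day 1), 33.7 (WT), -34.9 (KO) and monocyte-like -9.12 (day 1), -7.70 (WT), 17.7 (KO). With doublets kept, the values were neutrophil-like -46.4 (day 1), -28.5 (WT), macrophage-like 43.6 (day 1), -34.4 (day 3), 37.8 (WT), -40.2 (KO) and monocyte-like -12.95 (day 1), 11.8 (day 3). Under thinning to the shallowest library, the values were neutrophil-like -39.96 (day 1), -21.6 (WT), macrophage-like -29.1 (day 3), 30.7 (WT), -45.6 (KO) and monocyte-like -12.8 (day 1), 12.8 (day 3), -3.37 (WT), 22.3 (KO). Given resolution 2, the values were neutrophil-like -37.05 (day 1), -1.95 (reversed, day 3), -14.3 (WT), 20.8 (KO), macrophage-like 39.1 (day 1), -17.2 (day 3), 27.8 (WT), -28.5 (KO) and monocyte-like -9.04 (day 1), -9.57 (WT), 14.9 (KO). With each library clustered alone, the values were neutrophil-like -36.04 (day 1), -9.08 (reversed, day 3), -15.97 (WT), 10.99 (KO), macrophage-like 41.9 (day 1), -11.4 (day 3), 29.97 (WT), -23.4 (KO) and monocyte-like -11.8 (day 1), -11.2 (WT), 16.1 (KO). Under doublets removed at the expected rate, the values were neutrophil-like -42.4 (day 1), 24.3 (KO), macrophage-like 34.9 (day 1), -34.8 (day 3), 37.2 (WT), -32.5 (KO) and monocyte-like -8.29 (day 1), -6.83 (WT), 17.7 (KO). Given clustering without long-intron genes, the values were neutrophil-like -41.01 (day 1), 2.46 (day 3), -22.4 (WT), 21.03 (KO), macrophage-like 48.8 (day 1), -17.9 (day 3), 31.4 (WT), -35.3 (KO) and monocyte-like -12.2 (day 1), 9.53 (day 3), 16.2 (KO). With all kept cells as denominator, the values were neutrophil-like -37.8 (day 1), 1.34 (day 3), -19.3 (WT), 19.8 (KO), macrophage-like 31.5 (day 1), -30.3 (KO) and monocyte-like 8.87 (day 3), -3.58 (WT), 14.9 (KO). Under the empty-droplet test, the values were neutrophil-like 0.447 (day 3), 20.6 (KO), macrophage-like 44.9 (day 1), -22.97 (day 3), 32.05 (WT), -35.8 (KO) and monocyte-like 10.9 (day 3), 17.2 (KO).

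Median log2 ratios of the efferocytosis list in macrophage-like cells and the apoptosis lists in neutrophil-like cells, KO against WT, follow for the settings in which they moved or turned. For total CPM, the medians were efferocytosis genes 0.63 (day 1), efferocytosis genes 0.61 (day 3, reversed), apoptosis-promoting genes 0.39 (day 1, reversed), apoptosis-promoting genes -0.55 (day 3) and apoptosis-opposing genes 0.36 (day 1, reversed). Under size factors, the medians were efferocytosis genes 0.14 (day 1) and efferocytosis genes 0.0495 (day 3, reversed). With no low filter, the medians were efferocytosis genes 0.0195 (day 1), apoptosis-promoting genes 0.0015 (day 1, reversed) and apoptosis-opposing genes 0.0714 (day 3). For each library clustered alone, the medians were efferocytosis genes 0.35 (day 1), apoptosis-promoting genes -0.58 (day 1) and apoptosis-opposing genes 0.0471 (day 3). Under doublets removed at the expected rate, the median of efferocytosis genes was 0.36 (day 1). With clustering without long-intron genes, the medians were efferocytosis genes 0.15 (day 1) and apoptosis-promoting genes -0.63 (day 1). For genes with under 10 kb of intron, the medians were efferocytosis genes -0.99 (day 1, reversed), efferocytosis genes -0.38 (day 3), apoptosis-promoting genes 0.20 (day 1, reversed) and apoptosis-opposing genes 0.0714 (day 3). Under the intron-length trend removed, the medians were efferocytosis genes -0.0048 (day 1, reversed), apoptosis-promoting genes 0.11 (day 3, reversed), apoptosis-opposing genes -0.24 (day 1) and apoptosis-opposing genes 0.73 (day 3). With background subtraction, the median of efferocytosis genes was -0.0151 (day 3). For cells thinned to 500 UMIs, the medians were efferocytosis genes 0.0599 (day 3, reversed) and apoptosis-opposing genes -0.14 (day 1). Under a UMI minimum of 1000, the medians were efferocytosis genes -0.0139 (day 3) and apoptosis-promoting genes -0.52 (day 1). With doublets kept, the medians were apoptosis-promoting genes -0.12 (day 1) and apoptosis-opposing genes -0.11 (day 1). For naming of mixed clusters, the median of apoptosis-opposing genes was -0.23 (day 1). A prior of 1 CPM left all 6 medians close to their values. The shift under total CPM comes with its construction, since it moves all ratios of a comparison by nearly the same amount, while for the other settings the cause was not tested.

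Of 296 results for single genes, total CPM left 130 close, moved 161 without a change of direction and turned 5. Size factors left 266 close, moved 29 and turned 1, and a prior of 1 CPM left 150 close and moved 146, which pulls less toward 0 by construction. Leaving out the low filter left all 296 as they were. Background subtraction left 256 close, moved 34 and turned 6, cells thinned to 500 UMIs left 95 close, moved 193 and turned 8, and removal of the intron-length trend left 179 close, moved 108 and turned 9. Cells thinned to 500 UMIs reversed Areg 0.37 (macrophage-like, WT), Mertk -0.24 (neutrophil-like, day 1), Mertk -0.0121 (monocyte-like, WT), Mfge8 -0.25 (macrophage-like, day 1), Cd36 -0.59 (macrophage-like, WT), Mcl1 0.23 (neutrophil-like, WT), Bax -0.57 (neutrophil-like, day 1) and Fas -0.64 (monocyte-like, day 1). Background subtraction reversed Egf -0.33 (macrophage-like, day 1), Egf -0.0780 (neutrophil-like, day 1), Egf -0.13 (monocyte-like, day 1), Egf 0.17 (monocyte-like, KO), Axl -0.22 (neutrophil-like, WT) and Cd36 -0.18 (neutrophil-like, WT). The intron-length trend removed reversed Mertk -0.14 (monocyte-like, day 1), Cd36 -0.0048 (macrophage-like, day 1), Mcl1 0.0034 (macrophage-like, KO), Mcl1 0.0563 (monocyte-like, day 1), Mcl1 0.40 (monocyte-like, day 3), Mcl1 0.0155 (monocyte-like, WT), Bcl2 -0.63 (macrophage-like, day 1), Bcl2 -0.67 (monocyte-like, day 3) and Bax 0.13 (monocyte-like, day 3). Total CPM reversed Mcl1 0.0616 (macrophage-like, KO), Mcl1 0.34 (neutrophil-like, WT), Mcl1 0.0459 (monocyte-like, day 3), Mcl1 0.0354 (monocyte-like, WT) and Fas 0.41 (neutrophil-like, day 1). Size factors reversed Mcl1 0.0157 (macrophage-like, KO). Apart from total CPM, the cause of these turns was not tested.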

Other observations

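The tests of the intron-length gap as a counting or preparation difference and as an effect of EGFR loss, and the test of EGFR loss for genes set apart in 1 library, were chosen only after the result was seen. Tubule cells other than proximal ones, which CD11b-Cre should spare, carried Egfr at 29.6 CPM in WT day 1, 80.0 in KO day 1, 38.9 in WT day 3 and 93.0 in KO day 3. Whether the intron-length gap accounts for the higher KO values was not tested. Haemoglobin transcripts, a trace of blood, made up 0.0793% and 0.2908% of neutrophil-like UMIs in WT and KO day 1 but 0.0014% and 0.0024% at day 3, while in empty droplets they were higher at day 3. All 4 libraries read as male, with Y-linked Ddx3y at 79.6, 60.1, 32.5 and 121 CPM in WT day 1, KO day 1, WT day 3 and KO day 3, and 0, 7, 2 and 0 UMIs of Xist, the transcript of the inactive X chromosome.

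Macrophage-like cells of WT and KO hardly shared clusters. The largest group of KO day 1 was cluster 1 (4385 of 7284 cells), that of WT day 1 cluster 18 (606 of 761), that of WT day 3 cluster 2 (2490 of 4168) and that of KO day 3 cluster 14 (382 of 668). Neutrophil-like cells split in the same manner, with cluster 3 for WT day 1 (2002 of 2504), cluster 6 for WT day 3 (1457 of 1982) and cluster 4 for KO day 1 (603 of 650) and KO day 3 (1100 of 1144). Clusters made up of 1 genotype may reflect its libraries rather than a cell state, and clustering without long-intron genes left the KO minus WT difference in neutrophil-like cells at -41.0 points at day 1 but shrank the day 3 differences to 2.46 in neutrophil-like, -17.9 in macrophage-like and 9.53 in monocyte-like cells.

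Ratios of KO to WT were higher for genes of long introns in every leukocyte class examined. Loss of EGFR in myeloid cells is argued against as the whole source, since the gap in T cell-like and B cell-like cells, which CD11b-Cre should spare, was at least 1.0887 times that in macrophage-like cells. More nuclear RNA is argued against too, because the nuclear RNAs Malat1 and Neat1, chosen for this test, had a median log2 ratio of -0.7834. A difference between genotypes in library preparation or in the counting of intronic reads is a candidate explanation, from the same T cell-like to macrophage-like ratio of 1.0887 at the smaller of the 2 days. It stays confounded with genotype. At day 1 the gaps were only -0.10 in empty droplets and 0.13 in proximal tubule cells (1.26 and 2.36 at day 3). They were wider at day 1 in other tubule cells, at 1.31, and in endothelial cells, at 0.90. WT day 1 proximal tubule cells had a median of 28.7% ribosomal RNA-like UMIs. Whether all RNA of a library shared the difference at day 1 therefore stays open.

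A set of 5 genes, picked after their values were seen, was present or near absent in 1 library alone across at least 4 of 7 classes. Lhfpl4 was present in WT day 1 (120 CPM in macrophage-like cells, against 0.11 in KO day 1) and Gm10260 near absent there (4.54 CPM against 210 in KO day 1), while in WT day 3 Gdpd3 was present (377 CPM against 13.7 in KO day 3) and Trim12a and H2-Eb1 were near absent (0.06 and 48.8 CPM against 15.7 and 1255). A gene altered in both KO libraries could not enter this set, so the set cannot test loss of EGFR in general. For these 5 genes loss of EGFR is argued against, since each set a WT library apart from the other WT library too. Of them, 60.0% were set apart in the WT day 3 library and in lymphoid classes too. Inherited differences between animals and a difference in how reads of overlapping genes were counted cannot be told apart here: random gene sets of this size had no genes close together either, which left percentile 49.1 without meaning, and 4 of only 5 genes overlapped another gene, 40.8282 points above the measured genes. Limiting the set to genes with little intron, which was also run, left 4 genes and the same reading.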
